A study of Homo sapiens with 4 samples.

How the data were processed

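Small RNA was sequenced from HaCaT cells, an immortalised human keratinocyte line, 24 h after treatment with the solvent DMSO or with RASP. Each treatment had 2 libraries, which the labels call a and b. Per the labels' protocols, the small RNA fraction was prepared with the PureLink RNA mini and mirVana kits, libraries were built with version 2 of the Ion Total RNA-Seq kit, and sequencing used a semiconductor instrument. Nothing in the labels says that libraries a and b came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

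The deposited table held 2565 rows, each a mature microRNA arm. Per the submitters' processing notes, FastQC, Bowtie2, SAMtools and HTSeq were used with the human builds named hg38 and GRCh38, and versions were not given. How reads that match several precursors were assigned, and whether strand was used, is not given in the sources used here. The authors deposited whole-number read counts per microRNA and library, which were not normalized. A second set of columns held RPKM values, which the authors derived from these counts with the length of the mature microRNA and a library total. That total, recovered from the deposited RPKM values, was 276335 and 225811 reads for DMSO libraries a and b, and 299537 and 273199 for RASP libraries a and b. The counted reads made up 94.2%, 92.9%, 94.3% and 94.3% of these totals. The remaining deposited columns held the mean RPKM of each group, a fold change and a p-value. The deposited fold change column is headed as log2, but in all 1512 rows with a number it equalled log10 of the ratio of the mean RPKM values within 1e-09, and in 0 rows did a value other than 0 equal log2 of that ratio. Values quoted from it were therefore multiplied by 3.32 to give log2. The deposited p-value equalled an unequal-variance comparison of the RPKM values in all 2222 rows with a number. The other cells of both columns held spreadsheet error text.

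All comparisons were computed here from the deposited counts. Of the 2565 rows, 343 were at 0 in all 4 libraries, and 0 rows named no microRNA. Libraries held 209754 to 282345 counts. Levels are given as CPM, the count of a microRNA per 1000000 counted reads of its library. A count of 0 allows a level of up to 3 counts, or 10.6 to 14.3 CPM in these libraries. Shares of a single library carry exact Clopper-Pearson 95% intervals. Reads carried no molecular identifiers that the labels name, so intervals of shares and floors cover counting error only. The same holds for the counting intervals of ratios of summed CPM. These pool the reads of the 2 libraries of a group and leave out the spread between libraries.

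RASP was compared with DMSO with edgeR 4.0.16 (R 4.3.3), using TMM scaling, filterByExpr by group with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fits and 2-sided quasi-likelihood F tests. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Of all rows, 309 were tested, which held 98.9% of counts. Standard errors were taken from the fold change and its F statistic, and 95% intervals from the fit's degrees of freedom. With 2 libraries against 2, an exact permutation test of a single microRNA cannot give a p below 0.333, so none was used. Lists of microRNAs were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and with an estimated correlation and the fry test as alternatives. Of 26 lists, 18 had at least 3 tested members and were tested.

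The groups, the test, the 26 lists and the alternative settings named first below were set before the data were examined. So was the rule for named microRNAs. It took, in each direction, up to 10 passing microRNAs whose groups did not overlap, or up to 5 of the lowest p where too few passed, then the 5 most abundant, and from each list up to 4 passing members or else the 2 most abundant. MicroRNAs named outside this rule are marked as chosen after their values were seen. These alternatives were edgeR's RLE size factors, upper-quartile scaling, no filter on low counts, at least 10 counts in all libraries, DESeq2 1.42.0, limma-voom, the letters a and b as a block, and leaving out each library in turn. Scaling by total counts only, a correction for GC content and combinations of the block with other tools or scalings were chosen after seeing the data. A setting meant for tables without counts did not apply, and keeping only rows named as microRNAs would have removed no row.

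The fitting code was tested on simulated counts drawn from the means and totals of these libraries. In 20 runs of the RASP against DMSO comparison with 200 changed rows among a median of 312 tested, the quasi-likelihood test recovered 15.7% of 2-fold and 62.6% of 4-fold changes, and 2.85% of its calls were false. With 20 changed rows per run, it recovered 1.57% of 2-fold and 31.8% of 4-fold changes. Intervals held the true change in 94.7% of cases. In runs with no change simulated, 0.3 rows were called per run. These simulated libraries held no difference between letters a and b, which the measured libraries did show, so the figures may not carry over.

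Positions are from GENCODE release 29 on GRCh38, matched by precursor name for 2562 of the 2565 rows. Of these rows, 173 had more than 1 precursor gene, and their reads cannot be assigned to a single locus. Members of the let-7, miR-30, miR-181, miR-19, miR-29, miR-200 and miR-520 groups have near-identical sequences, so their separate counts are uncertain. All columns of per-sample values in the table were assigned to these 4 libraries.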

Results

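The study profiled mature microRNAs in HaCaT cells, an immortalised human keratinocyte line, 24 h after treatment with RASP or with the solvent DMSO. The series title describes the compound under study as a synthetic conjugate of all-trans retinoic acid (atRA), a vitamin A derivative, with a polyamine. There were 2 libraries per group. DMSO libraries a and b held 260341 and 209754 counted reads, and RASP libraries a and b held 282345 and 257530. Reads were found for 1535 and 1421 microRNAs in the DMSO libraries and for 1483 and 1362 in the RASP libraries. All library pairs, within groups as well as between them, differed beyond counting error alone. The chi-square per degree of freedom lay between 17.9 and 83.6, the highest for the 2 RASP libraries.

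The microRNA pool of these cells was dominated by miR-205-5p, a microRNA of stratified epithelia, and by miR-21-5p, which is abundant in many dividing cells. miR-205-5p made up 39.4% ± 0.675 (SD, n = 2) of counts with DMSO and 38.9% ± 8.27 (SD, n = 2) with RASP. In single libraries its share was 38.9% (95% interval 38.7 to 39.1) and 39.9% (39.7 to 40.1) with DMSO, and 33.0% (32.9 to 33.2) and 44.7% (44.5 to 44.9) with RASP. The 2 RASP libraries thus lay on either side of both DMSO libraries. miR-21-5p took 18.04% and 12.97% of DMSO libraries a and b and 19.1% and 10.5% of RASP libraries a and b. The 10 most abundant microRNAs of each library, which included miR-19b-3p, miR-23a-3p and let-7f-5p, together held 72.7% ± 2.16 (SD, n = 2) of counts with DMSO and 73.9% ± 0.987 (SD, n = 2) with RASP.

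**Figure D1:**
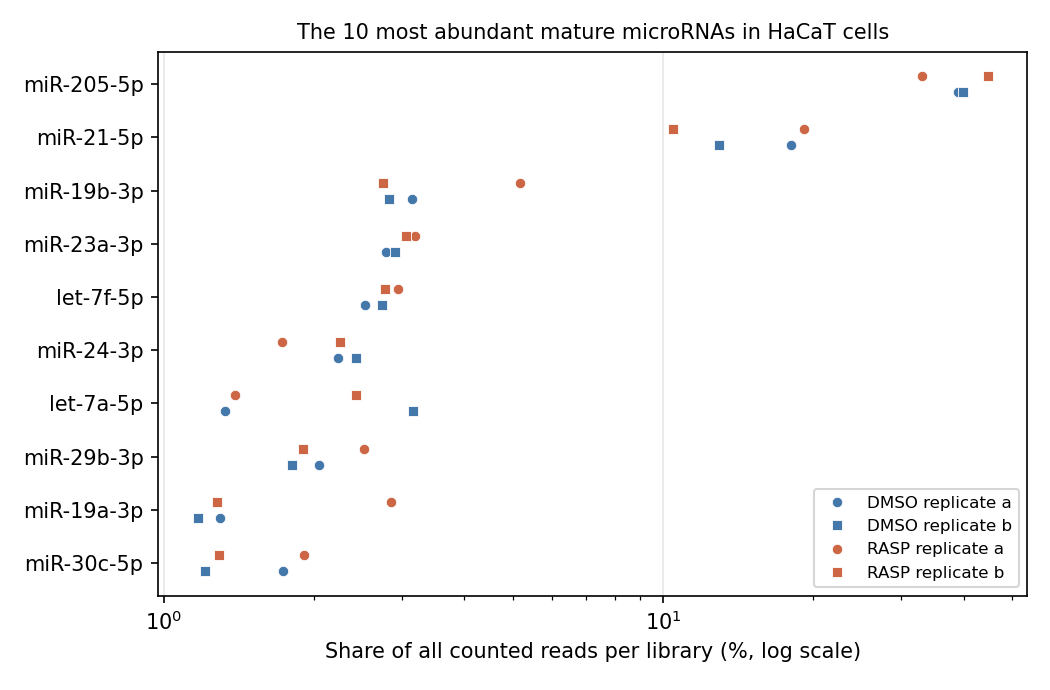
Share of all counted reads (percent, log scale) of the 10 microRNAs with the highest mean level, with a point for each DMSO and RASP library. miR-205-5p lies between 33.0% and 44.7% in all 4 libraries, and miR-21-5p between 10.5% and 19.1%.

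MicroRNAs typical of keratinocytes and epithelia were abundant in both groups. The keratinocyte list, with miR-205-5p, miR-24-3p and miR-31-5p among its members, summed to 44.4% ± 0.923 (SD, n = 2) of counts with DMSO and 43.4% ± 8.98 (SD, n = 2) with RASP. Most of these sums was miR-205-5p alone, with 39.4% and 38.9% of counts, so they say little about the other members. The miR-200 family, which maintains the epithelial state, summed to 2.68% ± 0.173 and 2.996% ± 0.177 (SD, n = 2 each). MicroRNA lists of other cell types were low. Muscle microRNAs summed to 25.4 ± 2.16 CPM with DMSO and 27.8 ± 0.815 CPM with RASP (SD, n = 2 each), and blood cell microRNAs to 48.3 ± 19.4 and 62.8 ± 6.40 CPM. Melanocyte microRNAs summed to 9.07 ± 7.40 and 5.65 ± 2.99 CPM, and the hepatocyte microRNA miR-122 to 7.15 ± 10.1 and 5.48 ± 2.26 CPM. These means lay below the level of 3 counts in each library (10.6 to 14.3 CPM), which DMSO library b reached for both with 14.3 CPM. The endothelial microRNA miR-126 summed to 83.2 ± 3.64 and 111 ± 19.01 CPM, and the mesenchymal list to 645 ± 137 and 759 ± 255 CPM. The neuronal list summed to 990 ± 36.3 and 994 ± 137 CPM, of which miR-128-3p, found in many cell types, made up 797 and 798 CPM.

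**Figure D2:**
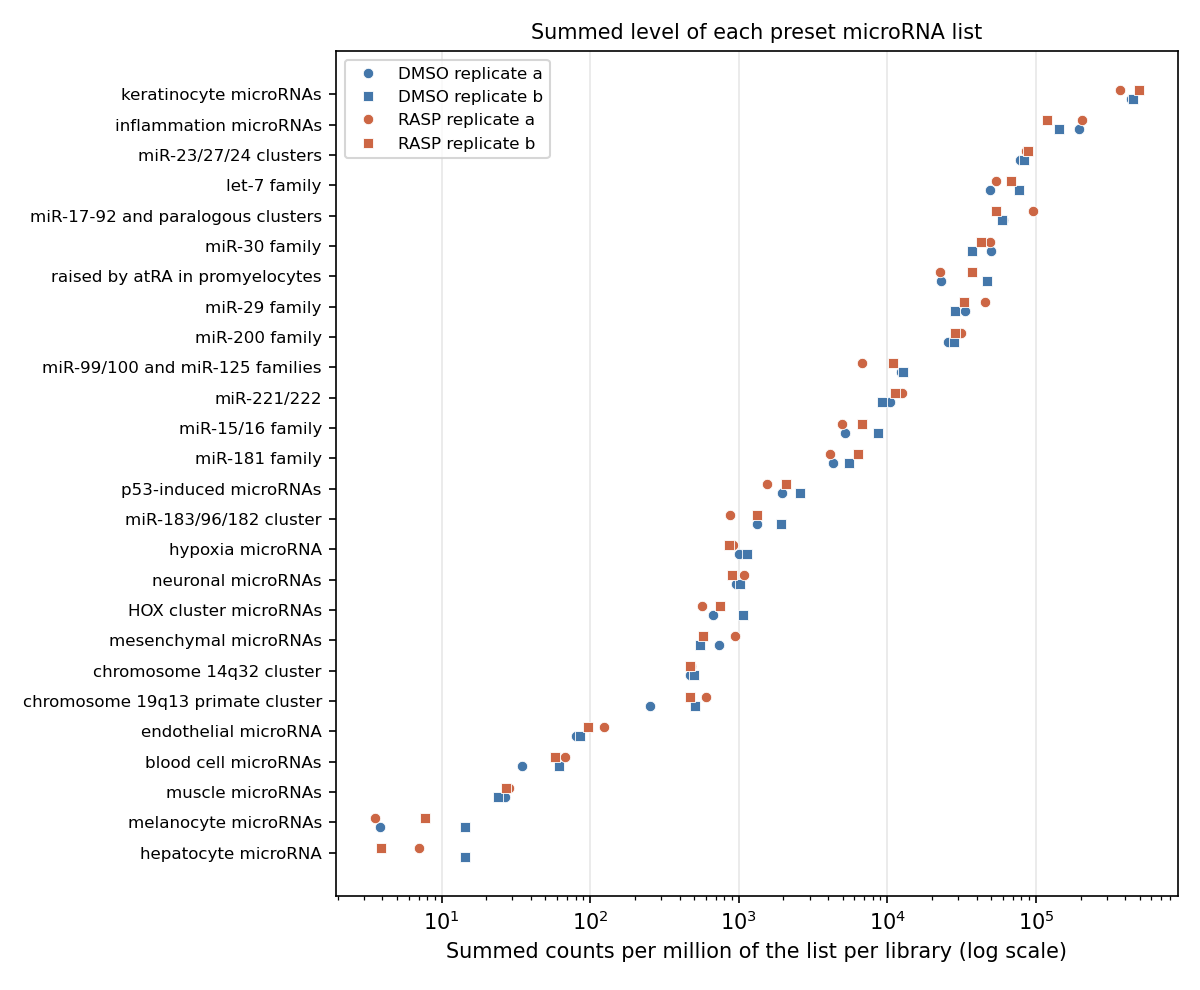
Summed level of each microRNA list in CPM (log scale), with a point for each DMSO and RASP library. Lists run from keratinocyte microRNAs, the most abundant, down to the hepatocyte microRNA, whose DMSO library a is at 0 and is not drawn.

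The comparison of RASP with DMSO asked which microRNAs the treatment altered. No microRNA passed the test in either direction. Among the microRNAs with the lowest p, miR-190a-5p, miR-3613-5p and the epithelial miR-200a-3p had higher levels with RASP, and miR-6751-3p, miR-1973, miR-330-3p and miR-598-5p had lower levels, but in the fit by group none of these differences exceeded the spread between libraries after adjustment. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 309 microRNAs higher and 0 lower, with a lowest adjusted p of 0.524. At an unadjusted p under 0.05 it gave 19 microRNAs, 4 higher and 15 lower, where 15.5 are due by chance. This split depended on the scaling, with 8 higher and 13 lower by edgeR's RLE size factors, 14 and 12 with upper-quartile scaling and 1 and 20 with total counts only. Fitted by group, DESeq2 and limma-voom also called 0, with 6 and 21 microRNAs at an unadjusted p under 0.05. The fit with letters a and b as a block, described below with the processing, gave calls that depended on the tool and the scaling. By CPM alone, both RASP libraries lay above both DMSO libraries for 33 microRNAs and below them for 86. Together these were 38.5% of those tested, where chance gives 33.3%, or 16.7% in each direction. CPM is scaled by total counts only, which shifted the median log2 fold change by -0.19 from TMM scaling. The uneven split of 33 and 86 thus also depends on the scaling.

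Of the 5 microRNAs with the lowest p among those higher with RASP, miR-200a-3p was the most abundant. It had 1241 and 753 counts in DMSO libraries a and b and 2275 and 1549 in RASP libraries a and b, or 4178 ± 832 and 7036 ± 1444 CPM (SD, n = 2 each). Its log2 fold change was 0.92 (SE 0.35, 95% interval 0.07 to 1.77), with an adjusted p of 0.637 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its gene MIR200A lies between genes on chromosome 1 (1167863 to 1167952, plus strand). miR-22-3p had 1862 ± 98.6 CPM with DMSO and 2752 ± 230 CPM with RASP (SD, n = 2 each), a log2 fold change of 0.74 (SE 0.31). It comes from an exon of the noncoding gene MIR22HG on chromosome 17 (1713903 to 1713987, minus strand). miR-3613-5p, from an intron of DLEU2 on chromosome 13 (49996415 to 49996501, minus strand), had 169 ± 37.7 and 339 ± 64.0 CPM (SD, n = 2 each) and a log2 fold change of 1.20 (SE 0.40). miR-5006-3p, from an exon of VWA8 on chromosome 13 (41568286 to 41568395, minus strand), had a log2 fold change of 1.30 (SE 0.50). The scarcest of the 5 was miR-190a-5p, from an intron of TLN2 on chromosome 15 (62823957 to 62824041, plus strand), with 4 and 3 counts in the DMSO libraries against 15 and 10 with RASP. Its log2 fold change was 1.77 (SE 0.57). The ratio of summed CPM was 3.11, with a counting interval of 1.31 to 8.52 that leaves out the spread between libraries. All 5 were higher in both RASP libraries than in both DMSO libraries. Other arms of the same precursors, chosen after their values were seen, did not all go the same way. miR-200a-5p had 36 and 28 counts with DMSO against 27 and 25 with RASP, and miR-3613-3p had 36 and 31 against 37 and 23. miR-22-5p had 341 and 247 against 455 and 346.

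The microRNAs lower with RASP at the lowest p were scarce. miR-6751-3p, from an exon of SYVN1 on chromosome 11 (65129916 to 65129978, minus strand), had 16 and 20 counts in the DMSO libraries and 3 in each RASP library. Its log2 fold change was -2.57 (SE 0.57, 95% interval -3.97 to -1.17) with an adjusted p of 0.524 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. miR-1973 had 44 and 20 counts against 5 and 4, a log2 fold change of -2.80 (SE 0.62). Its precursor, in an exon of MTRNR2L13 on chromosome 4 (116299725 to 116299768, plus strand), shares sequence with the mitochondrial ribosomal RNA gene MT-RNR2, so its reads cannot be assigned to either with certainty. miR-330-3p, from an exon of EML2 on chromosome 19 (45638994 to 45639087, minus strand), had 15 and 13 counts against 2 and 3, a log2 fold change of -2.44 (SE 0.59), and a ratio of summed CPM of 0.155 with a counting interval of 0.0469 to 0.408. miR-598-5p, from an intron of XKR6 on chromosome 8 (11035206 to 11035302, minus strand), had 68 and 42 counts against 11 and 15, a log2 fold change of -2.07 (SE 0.52). miR-4492, between genes on chromosome 11 (118910708 to 118910787, plus strand), had 11 and 29 counts against 3 and 2, a log2 fold change of -3.00 (SE 0.78). Of the fits that left out 1 library, it passed in the one without DMSO library a, with an adjusted p of 0.00094 by the same test, and its adjusted p ran up to 0.986 over the settings tried.

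**Figure D3:**
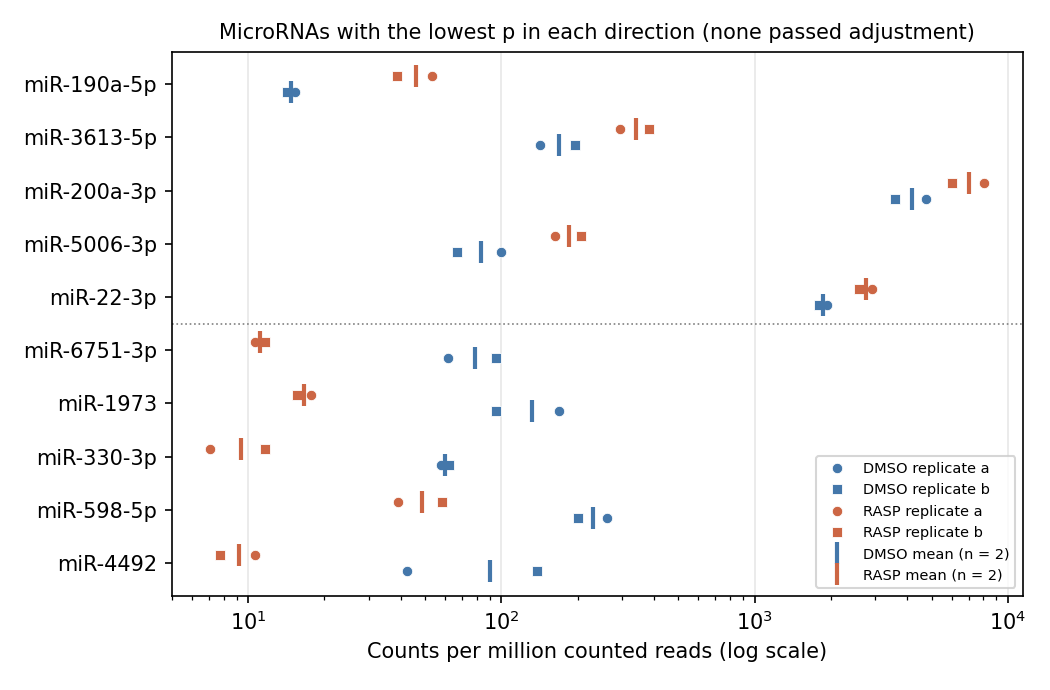
Level in CPM (log scale) of the 5 microRNAs with the lowest p in each direction, with a point for each DMSO and RASP library and a bar for each group mean (n = 2). miR-200a-3p lies between 3590 and 4767 with DMSO and between 6015 and 8057 with RASP, and none of the 10 passed after adjustment in the fit by group.

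None of the 5 most abundant microRNAs passed, and their intervals included 0. Those of miR-205-5p, miR-23a-3p and let-7f-5p lay within 2-fold either way, and those of miR-21-5p and miR-19b-3p did not. miR-205-5p, from an exon of MIR205HG on chromosome 1 (209432133 to 209432242, plus strand), had a log2 fold change of 0.16 (95% interval -0.57 to 0.89). miR-21-5p, from an exon of VMP1 on chromosome 17 (59841266 to 59841337, plus strand), had 0.10 (-0.89 to 1.09), miR-23a-3p 0.31 (-0.37 to 0.995) and let-7f-5p 0.30 (-0.38 to 0.98). miR-19b-3p had 0.58 (-0.37 to 1.53), with estimates from 0.06 to 0.96 over the settings tried. Its 51664 CPM in RASP library a stood apart from 27531 CPM in RASP library b and from 31455 and 28319 CPM with DMSO. The estimates of miR-205-5p and miR-21-5p turned below 0 with scaling by total counts alone. They also did so in fits that left out 1 library, down to -0.075 and -0.40. Over all 309 microRNAs, 151 estimates lay above 0 and 158 below. The share above 0 was 48.9%, against 58.9% with upper-quartile scaling and 36.9% with total counts only, which shifted the median log2 fold change by 0.21 and -0.19.

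**Figure D4:**
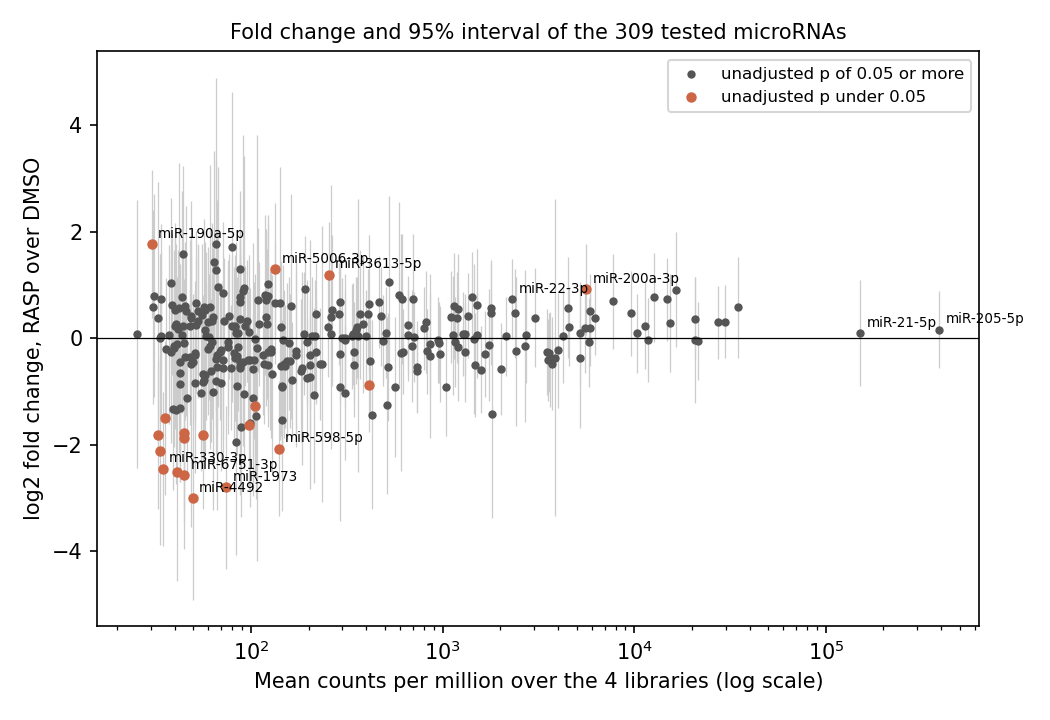
Log2 fold change of RASP over DMSO against mean level in CPM (log scale) for the 309 tested microRNAs, with 95% intervals as grey lines. The 19 microRNAs at an unadjusted p under 0.05 are mostly scarce and below 0, and none passed after adjustment in the fit by group.

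No list of related microRNAs passed the set test. Camera called 0 of the 18 lists tested, with 1 list at an unadjusted p under 0.05, and 0 lists were called by fry or with an estimated correlation. No list held a microRNA that passed over all 309 tested, and adjusted over the list alone the count was also 0 in every list. The lowest p belonged to the primate cluster on chromosome 19q13, which is active mainly in placenta. It had 3 tested members, among them miR-520g-3p with a log2 fold change of 0.80 (SE 0.56) and miR-520a-3p with 0.72 (SE 0.52), and a median of 0.80. Its adjusted p was 0.497 by camera with Benjamini-Hochberg adjustment, and p = 0.309 with an estimated correlation before adjustment. Without DMSO library b the cluster passed, with an adjusted p of 0.027 in a range up to 0.958 over the settings tried. Its members share most of their sequence.

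Among the lists named for a response to retinoids, microRNAs that atRA raises in leukaemic promyelocytes had 7 of 11 tested members above 0 and 4 below. Their median log2 fold change was 0.04, their mean -0.02 and the direction of camera up, with an adjusted p of 0.883. let-7a-5p had -0.03 (95% interval -1.21 to 1.16) and let-7d-5p 0.04 (-0.84 to 0.93). Of 5 tested microRNAs of the HOX clusters, genes that retinoids regulate in embryos, 2 lay above 0 and 3 below, with a median of -0.11 and a mean of -0.03 although camera gave the direction up, at an adjusted p of 0.952. miR-196a-5p had 507 ± 173 CPM with DMSO and 327 ± 37.0 CPM with RASP (SD, n = 2 each), a log2 fold change of -0.43 (SE 0.38). miR-10b-5p had 112 ± 71.2 and 127 ± 73.7 CPM (SD, n = 2 each), a log2 fold change of 0.39 (SE 0.68).

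Families of abundant microRNAs had small medians. In 9 of the 18 lists the median kept its sign under all 4 scalings, 7 above 0 and 2 below. A change of scaling shifts all microRNAs by nearly the same amount. A kept sign therefore restates the size of the median and gives no separate support. Above 0 were the miR-23/27/24 clusters (median log2 fold change 0.30, 7 of 10 members above 0), the miR-29 family (0.37, 3 of 5), the miR-30 family (0.22, 5 of 7), the miR-181 family (0.27, 4 of 5), miR-221 and miR-222 (0.38, 3 of 3), the miR-200 family (0.17, 6 of 9) and the 19q13 cluster. Camera's adjusted p was 0.510 for the miR-23/27/24 clusters and 0.585 for miR-221 and miR-222, the lowest after the 19q13 cluster. miR-29a-3p had 10086 ± 1158 CPM with DMSO and 15275 ± 4128 CPM with RASP (SD, n = 2 each), a log2 fold change of 0.77 (SE 0.34). miR-221-3p had 0.38 (SE 0.29) and miR-222-3p 0.57 (SE 0.39). Below 0 were the miR-99/100 and miR-125 families (-0.22, 5 of 6 below 0), with miR-125b-5p at -0.40 (SE 0.36) and miR-100-5p at -0.41 (SE 0.31), and the cluster of miR-183, miR-96 and miR-182 (-0.24, 3 of 4 below 0), with miR-182-5p at -0.91 (SE 0.54). Over the settings tried, these ran from -0.83 to -0.07, from -0.59 to -0.09 and from -1.63 to -0.38. Those of miR-29a-3p, miR-221-3p and miR-222-3p ran from 0.47 to 1.07, from 0.20 to 0.59 and from 0.24 to 1.06.

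The medians of the other lists changed sign with the scaling. The let-7 family had a median log2 fold change of -0.03 over 17 members, the keratinocyte list 0.07 over 14, the miR-15/16 family 0.13 over 8, p53-induced microRNAs 0.08 over 5, inflammation microRNAs 0.10 over 6 and the neuronal list 0.12 over 3. The miR-17-92 and paralogous clusters had a median of -0.19 and a mean of -0.02 over 14 members, while camera gave the direction up at an adjusted p of 0.898, and miR-19a-3p had 0.92 (SE 0.44), or 0.23 without RASP library a, which held 28476 CPM of it against 12802 CPM in RASP library b and 12979 and 11704 CPM with DMSO. Lists with fewer than 3 tested members were given no set test. The hypoxia microRNA miR-210-3p had -0.08 (SE 0.31), miR-126-3p 0.69 (SE 0.49), miR-143-3p 0.65 (SE 0.53) and miR-145-5p 0.08 (SE 0.39). In the chromosome 14q32 cluster, miR-493-5p had 1.59 (SE 0.68) with 4 and 7 counts against 11 and 23, and miR-665 had 0.41 (SE 0.53).

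In the authors' deposited table, 64 of 2222 rows had a p-value under 0.05, and 50 of these had 10 or fewer counts over the 4 libraries. An even spread of p-values would give 111. Rows with so few counts repeat the same few p-values, so 64 against 111 is no evidence for or against an effect. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 0 passed, with a lowest value of 0.795. Of the 64, 7 were among the 309 tested by edgeR, and 3 of those, miR-330-3p, miR-4497 and miR-762, also had an unadjusted p under 0.05 there, all lower with RASP. The last 2 names were chosen after their values were seen. For miR-330-3p the authors' deposited table gives a p-value of 0.00439 and a ratio of -2.66 on the log2 scale. For miR-200a-3p the authors' deposited table gives 0.163 and 0.76.

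The precision of the comparison was limited by the spread between libraries. That spread included the difference between letters a and b described below with the processing, which the fit by group counts as error. In the fit by group the biological coefficient of variation was 40.3%, and the median 95% interval reached 1.26 on the log2 scale to either side, or 0.84 for the 50 most abundant microRNAs, so that a 2-fold change either way was excluded for 25 of the 309.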

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

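Tests with total counts only, with a GC correction, and with the block joined to another tool or scaling were chosen after the result was seen. The counts of 0 higher and 0 lower held with size factors, upper-quartile scaling, both other filters, DESeq2, limma-voom and total counts only. Apart from the fit without a filter, these gave 6 to 26 microRNAs at an unadjusted p under 0.05. That fit gave 85 of 2222 tested. An even spread of p-values would give 111, but rows with few counts need not spread evenly, so the 2 numbers decide nothing. No list passed with size factors, no filter, the block, fry or an estimated correlation. Nothing in the labels pairs the letters. With the replicate block, 1 microRNA was higher (miR-200a-3p) and 9 lower, among them miR-1973, miR-330-3p, miR-598-5p, miR-6751-3p and miR-4492. With the replicate block and a GC correction the counts were 4 and 11, of which 9 were shared with the block alone. With the block in DESeq2 they were 0 and 1, and with the block in limma-voom, with size factors or with upper-quartile scaling 0 and 0, so these calls depended on the tool and the scaling. The lowest adjusted p was 0.110 to 0.152 in these 3 fits without calls. At an unadjusted p under 0.05 the block gave 63 microRNAs, and joined to another tool, scaling or GC correction 30 to 65, against 15.5 due by chance. The biological coefficient of variation was 24.5% with the block against 40.3% without it. In simulated libraries with a difference between letters and this smaller spread, the blocked fit recovered 40.04% of 2-fold changes, against 15.7% without a block in libraries simulated with neither. The differences between letters a and b correlated between the groups at 0.531 across microRNAs, which are not independent replicates, against -0.113 to 0.136 in simulated libraries without such a difference. A trend with precursor GC content is argued against as its source, since the correlation was 0.568 after removing each library's GC trend. It was 0.510 after thinning all libraries to 209754 counts, and 0.530 without miR-205-5p and miR-21-5p. These 2 values cannot decide on depth or on the shares of the most abundant microRNAs. Thinning leaves the expected CPM as they were, and a changed share shifts all other microRNAs alike, which a correlation ignores. A shared day or handling of each letter may be the source, but the labels name none and this was not tested. The GC trend is also argued against as the whole cause of the 10 calls under the block, since removing it left a median of 0.923 of their size. Leaving out 1 library gave 0 to 0 higher, 0 to 1 lower (miR-4492 without DMSO library a) and 0 to 1 lists (19q13 without DMSO library b, where the group left with 1 library is assumed to vary like the other). The cause was not tested. Of 50 named microRNAs with a test, 30 kept their sign in all alternatives. None of the others passed under any of these settings, and their log2 fold changes turned as follows. With size factors, the values were let-7a-5p 0.036, miR-24-3p 0.0089, miR-30a-5p 0.018 and miR-183-5p 0.011. With DESeq2, the values were let-7a-5p 0.036, miR-24-3p 0.0089, miR-30a-5p 0.018 and miR-183-5p 0.011. With upper-quartile scaling, the values were let-7a-5p 0.17, miR-24-3p 0.16, miR-30a-5p 0.18, miR-183-5p 0.16 and miR-210-3p 0.13. Without a filter, the values were let-7a-5p 0.20, miR-24-3p 0.15, miR-30a-5p 0.14, miR-183-5p 0.15 and miR-210-3p 0.10. With at least 10 counts in all libraries, the values were let-7d-5p -0.012 and miR-192-5p -0.046. With limma-voom, the values were let-7a-5p 0.023 and miR-192-5p -0.0036. Under the replicate block, the values were let-7a-5p 0.022 and miR-192-5p -0.0017. Under the block in limma-voom, the values were let-7a-5p 0.020 and miR-192-5p -0.0047. Under the block in DESeq2, the values were let-7a-5p 0.078 and miR-30a-5p 0.047. Under the block with size factors, the values were let-7a-5p 0.078 and miR-30a-5p 0.047. Under the block with upper-quartile scaling, the values were let-7a-5p 0.23, miR-24-3p 0.15, miR-16-5p 0.014, miR-30a-5p 0.20, miR-183-5p 0.15 and miR-210-3p 0.13. Under the block with a GC correction, the values were miR-30a-5p 0.041, let-7d-5p -0.00094 and miR-210-3p 0.49. With total counts only, the values were miR-205-5p -0.022, miR-21-5p -0.070, miR-181b-5p -0.13, let-7d-5p -0.15, miR-192-5p -0.18, miR-31-5p -0.089, miR-145-5p -0.097, miR-128-3p -0.0019 and miR-9-5p -0.049. Leaving out each library gave ranges of miR-24-3p -0.25 to 0.14, miR-30a-5p -0.24 to 0.35, miR-183-5p -0.27 to 0.15, miR-10b-5p -0.37 to 1.17, let-7d-5p -0.31 to 0.33, miR-21-5p -0.40 to 0.54, let-7a-5p -0.49 to 0.66, miR-16-5p -0.62 to 0.35, miR-34a-5p -0.62 to 0.025, miR-192-5p -0.080 to 0.12, miR-145-5p -0.11 to 0.43, miR-9-5p -0.52 to 0.69, miR-30c-5p -0.019 to 0.75, miR-143-3p -0.071 to 1.17, miR-205-5p -0.075 to 0.37, miR-181a-5p -0.073 to 0.73, miR-181b-5p -0.13 to 0.24 and miR-31-5p -0.12 to 0.28. At these depths, counts of 2 to 5 per library leave the scarce microRNAs with wide intervals.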

Other observations

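Of the tests below, the 1 on rows that share sequence with structural RNAs was chosen only after the result was seen, and the others were set once the pattern had been noticed but before their own values were known.

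Libraries b were also compared with libraries a, and the microRNAs named in this paragraph were chosen after their values were seen. miR-7154-5p was the single microRNA called in that comparison, with a log2 fold change of 4.63 (SE 0.67) and an adjusted p of 0.0196 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. miR-7-5p had -2.05 (adjusted p 0.0539) and let-7b-5p 1.15 (adjusted p 0.144) by the same test and did not pass. That split gave 45 microRNAs at an unadjusted p under 0.05, against 19 for RASP against DMSO and 1 for the crossed split.

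MicroRNAs with GC-rich precursors tended to have lower estimates with RASP. Across 308 microRNAs, which are not independent replicates, the Spearman correlation of precursor GC content with the log2 fold change was -0.258 (permutation p = 1e-04, the smallest the permutations can give, adjusted p 3e-04 over 6 relations), and it was -0.164 within letter a and -0.257 within letter b. Precursor GC content also correlated with level at -0.206, and level with the log2 fold change at 0.148. Part of the trend may therefore go with level, which was not tested. A bias of single libraries could also give such a trend. In the comparison of b with a the correlation was 0.0138, but the trend with RASP was too weak for that value to decide, so a library bias and a treatment effect cannot be told apart with 2 libraries per group.

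miR-1973 and miR-4485-3p, whose precursors share sequence with the mitochondrial ribosomal RNA gene MT-RNR2, had log2 fold changes of -2.80 and -1.26, the second chosen after its value was seen. A hypothesis is that fragments of structural RNAs may be fewer in the RASP libraries. The other 8 tested microRNAs found to share sequence with a structural RNA had a median of -0.521, with 7 below 0. The search covered classes annotated in GENCODE and left out nuclear transfer RNAs, so other rows of this kind may have been missed. That median lay at percentile 5.26 of 10000 lists matched on level, which does not settle the question. Such lists treat microRNAs as independent, and members that vary together would make the percentile look too extreme. With the first 2 included, the median was -0.57 at percentile 1.74, but they had prompted the test.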
